A study of Mus musculus with 6 samples.

How the data were processed

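RNA was measured in 6 libraries of mouse ES cells, 3 at day 0 and 3 at day 6. Per the labels' protocols, the cells were a reporter line grown on mouse embryonic fibroblast feeders or on gelatin. The strain label of each sample reads C57BL/6J, while the growth protocol names another strain for the line, and the labels do not settle which holds. Total RNA was isolated with Trizol, poly(A)-selected, prepared with an Illumina long RNA kit and sequenced on a HiSeq2000, per the labels' protocols. The submitters' processing notes list TopHat2 2.0.8, Cufflinks 2.1.1, HTSeq 0.5.4p3, DESeq without a version and the genome build mm9, with no role or order. Whether counting used strand, and how reads in shared exons were assigned, is not given in the sources used here.

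The deposited table holds a signal per assembled locus and library that the authors made by dividing read counts by one size factor per library. This was read from the values: in each column all values were whole multiples of one step, within a tolerance of 0.01 reads (100% of values). The size factors were 1.15, 0.966 and 1.00 for day 0 replicates 1, 2 and 3, and 0.986, 0.976 and 0.958 for day 6. For day 0 replicate 3 the step, 0.997, lies so close to 1 that an automatic test cannot tell it from rounding, and the reads of that library were used as recovered all the same. Recovered reads summed to 106306699 to 114092201 per library and normalized counts to 98581624 to 117818229. The 10 most abundant loci took 5.38 to 5.56% of the counts at day 0 and 6.25 to 7.16% at day 6. PCR reads without molecular identifiers are not independent molecules. Each column name matched the label of 1 sample. Columns left unused numbered 0.

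The other deposited file is the authors' merged assembly, with exon start and end positions and a class code per transcript against annotated genes. It holds 1458008 exon records. Loci were classed from that file alone. A locus with a transcript matching an annotated one was called coding where the file gives a protein identifier and noncoding where it gives none. A locus was called unannotated intergenic where all of its transcripts are, and unannotated antisense where transcripts lie on the strand opposite to annotated exons and none is an isoform of an annotated gene. The remaining 21 tested loci stayed out of the class tests. Positions are those of the file. Overlap was taken as the percentage of a locus's exonic bases that lie in exons of other loci on either strand; it was over 50% for 2535 of the 18420 loci in the table.

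Neither file pairs its identifiers with gene names. Of the 18420 locus identifiers and the 55308 annotation identifiers of the assembly, 0 matched the gene name tables used, so loci are given by identifier and position. For the same reason the 37 gene lists and the 22 key genes that had been fixed before the data were examined (521 symbols in the lists given by name) were not tested: 0 of these symbols occur in the files. The rule for named genes also asked for the 8 largest rises and falls among loci with a gene symbol, which none has, and for the 3 unannotated loci with the most exons, which are reported. The largest called rise and fall among annotated coding loci with no overlap between the stages, at least 10 normalized counts in every library and a mean of at least 200 in the higher stage were added after the values were seen. Larger falls, of loci with fewer than 10 counts in some library, lie outside that filter.

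Day 6 was compared with day 0 with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust estimation) on log2(normalized count + 1). Fold changes on this scale understate the change of low loci. A locus was tested with at least 10 normalized counts in at least 3 of the 6 libraries, which left out 1275 loci. Tests were two-sided and adjusted by Benjamini-Hochberg over the 17145 tested loci, with a threshold of 0.05. The day 6 fit had no block for replicate number. Classes were compared with Fisher's exact test across loci, also within quintiles of mean level, with an exact conditional test stratified by quintile for the direction of calls, and with an exact permutation test for their share of the counts. Position analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

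The steps were tested on simulated counts for 17145 loci of a simulated day 6 against day 0, with 50 loci changed at each of 4 fold sizes. limma recovered 4% of the loci changed 1.5-fold, 32% at 2-fold, 78% at 4-fold and 96% at 8-fold, with 7 false calls. edgeR 4.0.16 recovered 2%, 32%, 78% and 96% with 9 false calls, and DESeq2 1.42.0 recovered 8%, 46%, 92% and 96% with 56. The simulation changed far fewer loci than the 7543 called in the data, which makes the adjusted threshold stricter. It also gave each locus the same dispersion at both stages. These recovery rates therefore test the steps and do not give the power reached in the data. Small changes can still be missed with 3 libraries per stage.

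Alternatives fixed before the data were examined were a pseudocount of 0.5 or 5, no filter or a minimum of 50, rescaling by the trimmed mean of M values (TMM), quantile normalization, a replicate block and variance estimation without trend or robust fitting. edgeR's quasi-likelihood test and DESeq2 on the recovered reads, and leaving out each library in turn, were fixed too. edgeR called 7493 loci and DESeq2 8278. For the assembly, alternatives were a minimum length of 200 nt, at least 2 exons, and a distance of 5 kb. One alternative, restricted to loci with at most 10% of exonic bases shared, was chosen after seeing the data.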

Results

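Poly(A)-selected RNA was sequenced from mouse embryonic stem (ES) cells in the undifferentiated state (day 0) and from embryoid bodies, the aggregates that ES cells form in hanging drops, at day 6 after cardiac differentiation was induced. The cells carried a green fluorescent reporter for Nkx2.5, a gene of early heart cells, and were kept undifferentiated with LIF, a cytokine that maintains ES cells. Each stage had 3 libraries, described as biological replicates by the series' design text. The series' title sets the question: how the coding and the noncoding transcriptome differ between the stages. Counts were given for 18420 assembled loci, numbered by the assembly and placed on the mm9 genome. Day 0 libraries held 113005578, 113761382 and 106306699 counted reads for replicates 1, 2 and 3, and day 6 libraries held 113723157, 114092201 and 107362471. In the undifferentiated cells 83, 127 and 112 loci had no read, and in the embryoid bodies 191, 206 and 144.

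Undifferentiated cells and embryoid bodies formed separate groups of libraries. The first principal component of the log2 normalized counts held 80.7% of the variance and placed the day 0 libraries between -110 and -91.5 and the day 6 libraries between 93.6 and 107. Over 17145 loci, Pearson's r between a day 0 and a day 6 library averaged 0.900 ± 0.007 (SD over 9 pairs). Pairs of embryoid body libraries had a mean r of 0.994 ± 0.001 and pairs of undifferentiated libraries one of 0.974 ± 0.006 (SD, 3 pairs each). These correlations are across loci, which are not independent replicates. Undifferentiated cells varied more between replicates: the median SD of a locus was 0.40 on the log2 scale at day 0 and 0.14 at day 6. The second component, with 10.3% of the variance, separated the day 0 libraries, at 56.6, -67.8 and 14.8 for replicates 1, 2 and 3, from one another, while the day 6 libraries lay between -7 and 3.7. No pair of libraries of a stage agreed within sampling noise (chi-square per degree of freedom of at least 50), so none was treated as 1 library deposited again. This check covers counting error only, and that the libraries are separate replicates rests on the design text.

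**Figure D1:**
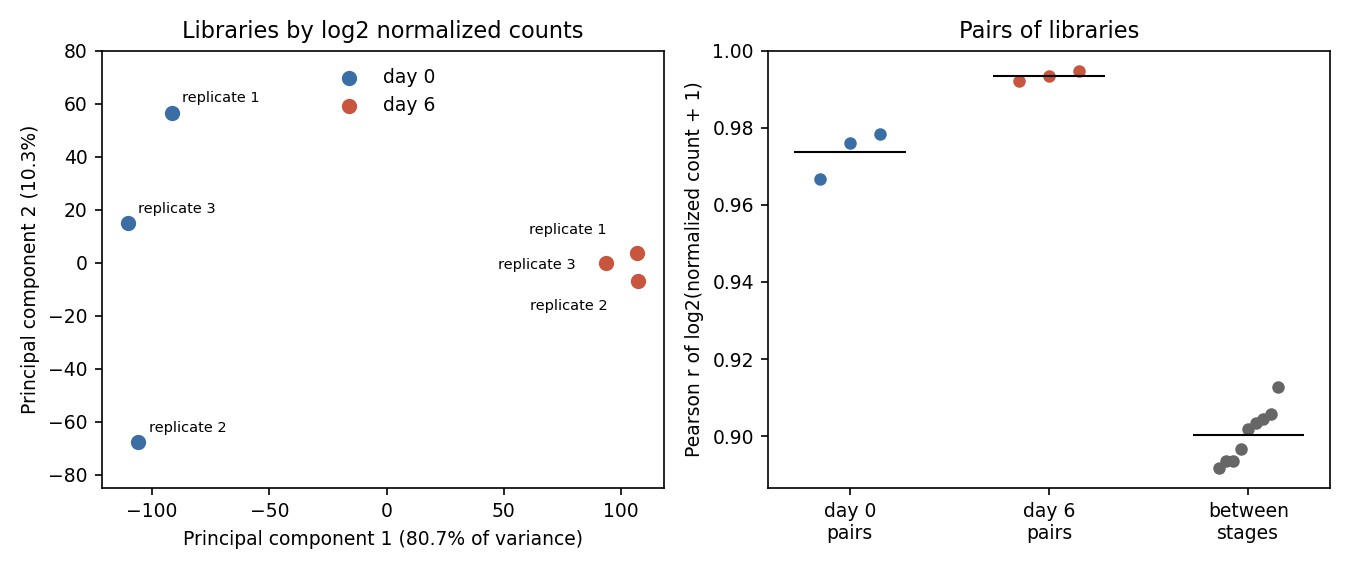
Left, the 6 libraries on the first (80.7% of the variance) and second (10.3%) principal components of log2(normalized count + 1), with day 0 in blue and day 6 in red. Right, Pearson's r for each pair of libraries, where points are pairs and lines are means (0.974 for day 0, 0.994 for day 6 and 0.900 between stages); pairs within a stage lie above all pairs between stages.

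Between the stages 7543 of the 17145 tested loci changed, which is 44% of them. Of these, 3799 were higher in embryoid bodies and 3744 were lower. A change of at least 2-fold was called for 5456 loci, 2469 higher and 2987 lower, and one of at least 8-fold for 602 higher and 538 lower loci. Calls used limma with a Benjamini-Hochberg adjusted p under 0.05. The fit took the spread as equal at both stages, although the median SD of a locus was 0.40 at day 0 and 0.14 at day 6. No fit with unequal spread was run, so how far the p-values and the number of calls depend on this was not tested. The median size of a called change was 1.54 on the log2 scale, against a median SE of 0.28 over all tested loci. The 3 values of one stage lay wholly above or below those of the other for 9820 loci, or 57.3%, where chance gives 10%. Among the 8591 loci with a mean of at least 1000 normalized counts, 3633 changed (42.3%). Of the loci called higher 17, of which 8 are unannotated and intergenic, had no read in any day 0 library, and of those called lower 15 had no read in any day 6 library. For these the fitted fold change depends on the pseudocount and no fold is given.

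The annotated coding locus XLOC_016830 rose 1050-fold. It lies on chromosome 18 at 53614380 to 53761257 on the plus strand (mm9), and has up to 10 exons per transcript. Its level was 17.6 ± 2.3 normalized counts at day 0 and 19593 ± 2542 at day 6 (SD, n = 3 each), a change of 10.04 on the log2 scale (SE 0.22, limma adjusted p = 2.73e-07). Of its exonic bases, 1.17% also lay in exons of other loci. Locus XLOC_008497, annotated as coding, went the other way. It spans 16102848 to 16126262 on the plus strand of chromosome 13, with up to 5 exons, and shares no exonic base with another locus. It was at 58714 ± 43175 normalized counts in undifferentiated cells and at 207.5 ± 39.2 in embryoid bodies (SD, n = 3 each), a log2 change of -7.82 (SE 0.55, limma adjusted p = 3.23e-05). Its day 0 replicates ranged from 17927 to 103935, all above the highest day 6 value of 238. Whether RNA of the feeders added to its day 0 counts was not tested. The log2 change was -8.51 without day 0 replicate 1 and -7.24 without day 0 replicate 2. Both loci were chosen after their values were seen, as the largest called rise and fall among annotated coding loci with no overlap between the stages, at least 10 normalized counts in every library and a mean of at least 200 in the higher stage.

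Among loci without an annotated gene, the 3 with the most exons had been set as examples before the data were examined. XLOC_004337, on chromosome 11 at 11937677 to 12097381 on the plus strand, has up to 17 exons and rose 3.91-fold. It went from 253.1 ± 47.5 to 985.4 ± 103 normalized counts (SD, n = 3 each), 1.97 on the log2 scale (SE 0.24, limma adjusted p = 0.000374). The other two did not pass the test. XLOC_001511, on chromosome 1 at 181623945 to 181665079 on the minus strand with up to 19 exons, was at 191.5 ± 108.9 in undifferentiated cells and 332.8 ± 59.1 in embryoid bodies (SD, n = 3 each; log2 change 0.94, SE 0.43, limma adjusted p = 0.108). It was called without day 0 replicate 1 (limma adjusted p = 0.0128) and with quantile normalization (log2 change 1.1, limma adjusted p = 0.049), and its adjusted p ran from 0.0128 to 0.26 over all alternatives. XLOC_003220, on chromosome 10 at 41309400 to 41412055 on the minus strand with up to 25 exons, was at 71.8 ± 44.9 and 33.2 ± 10 (SD, n = 3 each; log2 change -0.91, SE 0.54, limma adjusted p = 0.204). It was called without day 0 replicate 2, at -1.47 on the log2 scale and a limma adjusted p of 0.0193, the lowest in a range up to 0.479.

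**Figure D2:**
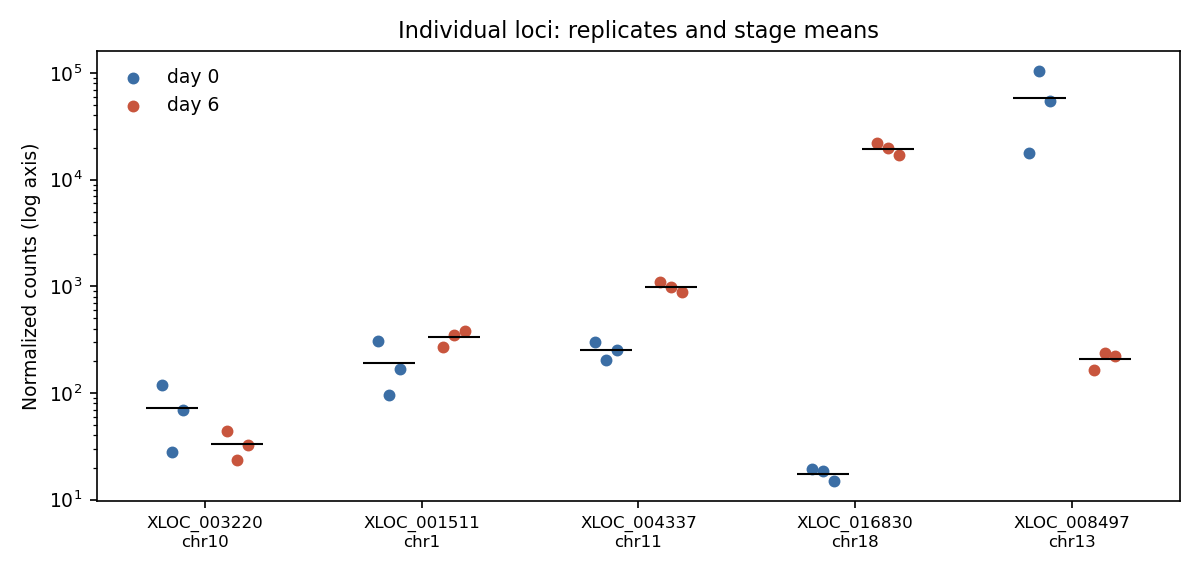
Normalized counts on a log axis for 5 loci, with 1 point per library (day 0 blue, day 6 red) and a line at the mean of each stage. The stages do not overlap at XLOC_004337, XLOC_016830 and XLOC_008497, and overlap at XLOC_003220 and XLOC_001511.

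Unannotated loci fell more often than they rose as ES cells formed embryoid bodies. They were defined by the merged assembly of these same stages, while annotated loci match an annotation. How far this difference between the classes shaped the direction and the share of changes was not tested. Of 1660 unannotated intergenic loci, 223 were higher at day 6 and 565 were lower, so that rises made up 28.3% of calls. Of 400 unannotated loci antisense to an annotated gene, 55 were higher and 124 lower (30.7% rises). Among 1305 annotated noncoding loci 234 were higher and 267 lower (46.7% rises), and among 13759 annotated coding loci 3284 were higher and 2784 lower (54.1% rises). Against coding loci, the odds of a rise among calls were 0.335 for intergenic loci (95% interval 0.283 to 0.395, adjusted p = 6.43e-43). They were 0.376 for antisense loci (0.268 to 0.523, adjusted p = 9.48e-10) and 0.743 for annotated noncoding loci (0.616 to 0.896, adjusted p = 0.00151). These were 3 two-sided Fisher's exact tests across loci, which are not independent replicates, and they were chosen after the split had been seen. Quantile normalization turned the order of the annotated classes, with 54% rises among noncoding and 49.5% among coding calls, and left 37.4% rises among intergenic and 38.3% among antisense calls. Intergenic loci had lower levels, with a median of 44.3 normalized counts per tested locus against 2069 for coding loci. The median size of a call was 2.21 on the log2 scale for intergenic and 1.40 for coding loci, but at like levels the sizes were close, at 2.48 and 2.42 in the lowest quintile of mean level and 2.02 and 2.01 in the second. Within the lowest quintile rises made up 30.4% of intergenic, 30.9% of antisense, 42.5% of annotated noncoding and 36.1% of coding calls. In the second they made up 25.5%, 31.8%, 47% and 39.2%, and in the third 25.9%, 31%, 56.6% and 54.1%. Stratified by quintile, the odds of a rise against coding calls were 0.597 for intergenic (95% interval 0.497 to 0.715, adjusted p = 2.26e-08) and 0.637 for antisense calls (0.45 to 0.894, adjusted p = 0.0102). For annotated noncoding calls they were 1.18 (0.971 to 1.44, adjusted p = 0.0929), so that their lower share of rises did not hold at like levels. These 3 two-sided exact conditional tests were chosen after the data were seen. They take the odds ratio as the same in every quintile, although the gap between coding and intergenic shares widened from the lowest to the third. In the lowest, which held 447 of the 788 intergenic calls, that gap was 5.7 points. They used the authors' normalization only, so whether the differences hold at like levels after quantile normalization was not tested. The counting is not stated to use strand, so reads in exonic bases that an antisense locus shares with its partner cannot be told apart; over 50% of exonic bases were shared for 110 of the 400 antisense loci. Among loci of all classes with at most 10% shared, rises made up 24.6% of antisense, 29.7% of intergenic and 53.3% of coding calls, a restriction chosen after the data were seen.

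**Figure D3:**
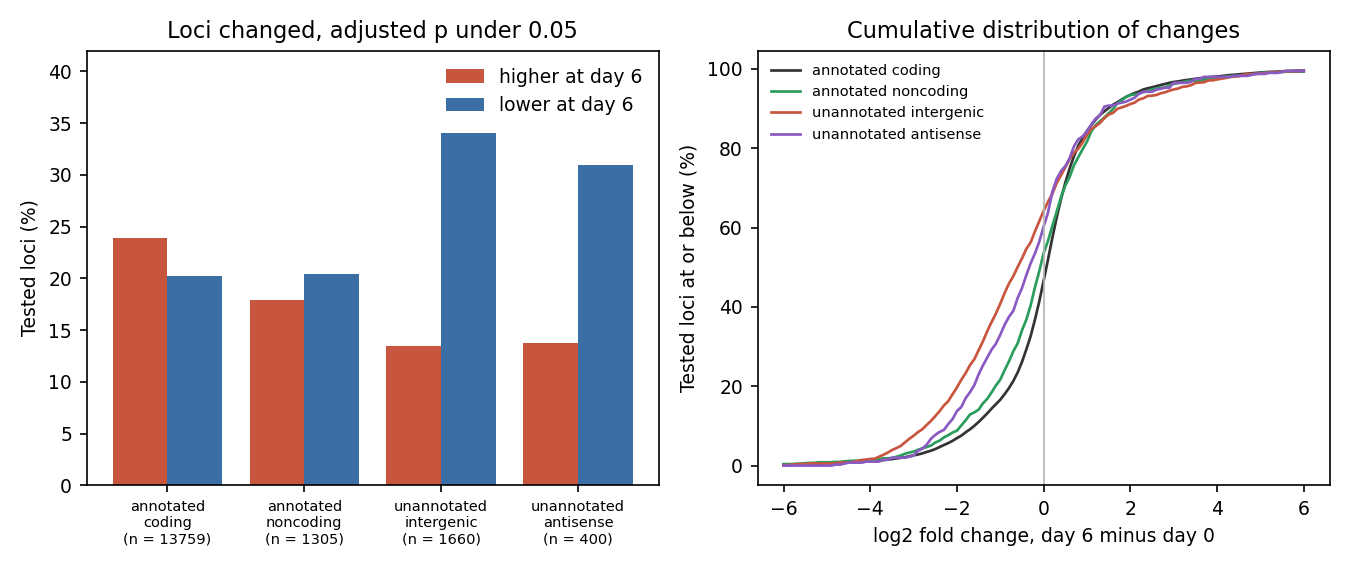
Left, the percentage of tested loci of each class that were higher (red) or lower (blue) at day 6 at a limma adjusted p under 0.05. Right, the cumulative percentage of tested loci against the log2 fold change (day 6 minus day 0) for each class; the intergenic curve lies above the coding curve left of 0, where its median is -0.61 and that of coding loci 0.06.

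Of the 3365 annotated noncoding, intergenic and antisense loci, pooled, 43.6% changed, against 44.1% of the coding loci, an odds ratio of 0.981 (95% interval 0.908 to 1.06, adjusted p = 0.799). Annotated noncoding loci changed less often, at 38.4% (odds ratio 0.79, interval 0.701 to 0.889, adjusted p = 0.000282), and intergenic loci more often, at 47.5% (1.15, 1.03 to 1.27, adjusted p = 0.0193). Antisense loci, at 44.8%, were not distinguishable from coding loci (1.03, 0.836 to 1.26, adjusted p = 0.799). The 4 comparisons used two-sided Fisher's exact tests across loci. In the lowest quintile of mean level, where 1704 of the noncoding and unannotated loci lie, 43.8% of these changed against 49.9% of coding loci (odds ratio 0.782, adjusted p = 0.00183), and in the other quintiles the odds ratio ran from 0.745 to 0.867 with no adjusted p under 0.0716. At like levels no intergenic excess was detectable: 46.2% of 967 intergenic and 49.9% of coding loci changed in the lowest quintile (odds ratio 0.862, 95% interval 0.733 to 1.01, adjusted p = 0.263), and 49.5% of 553 and 49% in the second (1.02, 0.846 to 1.24, adjusted p = 0.871). In the third, 50.9% of 114 intergenic and 45.4% of coding loci changed (1.25, 0.841 to 1.84, adjusted p = 0.63), an interval too wide to exclude an excess. Annotated noncoding loci changed less often than coding loci in the lowest and second quintiles, with odds ratios of 0.65 and 0.633 (adjusted p = 0.000156 each). These values are from 15 two-sided Fisher's exact tests, of 3 classes in 5 quintiles, chosen after the data were seen. Over all levels the intergenic excess was lost without day 0 replicate 1 (odds ratio 1.08, adjusted p = 0.214) and without day 0 replicate 2 (0.991, adjusted p = 0.876), and also without a filter, with quantile normalization and among loci with little shared sequence, over a range of adjusted p from 1.92e-12 to 0.876. Without these same libraries the pooled odds ratio was 0.902 (adjusted p = 0.015) and 0.824 (adjusted p = 1.11e-06), over a range from 3.37e-09 to 0.905. It turned to 1.17 at a minimum of 50 counts and to 1.26 with variance estimation without both trend and robust fitting. Under these 2 settings the ratio of annotated noncoding loci was 0.883 (adjusted p = 0.128) and 1.04 (adjusted p = 0.478), which ended that call, and the ratio of intergenic loci was 1.55 and 1.46.

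Coding loci held 95.5% ± 0.147 of the normalized counts in embryoid bodies and 94.9% ± 0.0732 in undifferentiated cells (SD, n = 3 each). The part of annotated noncoding loci was 4.52% ± 0.0511 at day 0 and 4.03% ± 0.135 at day 6. Intergenic loci held 0.407% ± 0.0253 and 0.297% ± 0.0115, and antisense loci 0.192% ± 0.0049 and 0.162% ± 0.0037. The 3 libraries of each stage did not overlap for any of these 4 classes. With 3 libraries against 3, the two-sided exact permutation test gave p = 0.1 for each, the smallest value the design allows. This test was chosen after the data were seen.

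Coding loci with over 10% of their exonic bases shared with other loci had fewer counts and fewer calls than those with none. The 8190 coding loci that share no exonic base had a median of 391 normalized counts per exonic kilobase, and 49.3% changed. With up to 10% shared (1262 loci) the median was 401 and 40.6% changed, and with 10 to 50% shared (2327 loci) it was 165 and 37.4% changed. Among 1765 coding loci with 50 to 90% of their exonic bases shared, the median was 40.6 and 33.7% changed. For the 215 with over 90% shared the values were 5.8 and 22.8%. Values of loci with much shared sequence are uncertain, since the way in which reads from shared exons were counted is not given in the sources used here.

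The merged assembly of both stages held 144343 transcript models in 40039 loci. Models that share a splice junction with an annotated gene without matching a transcript of it made up 43.0% (62119), and models matching an annotated transcript 41.5% (59973). Of these matching models 52720 had at least 2 exons, and the others have no intron chain to compare. Intergenic models without annotation numbered 17991 (12.5%) and antisense ones 2662 (1.84%). Only 6693 of the intergenic models had at least 2 exons, and 12924 lay at least 5 kb from every annotated transcript. Intergenic loci numbered 12765, of which 23.0% were spliced, and the 2075 of them with counts were all spliced. Coding loci numbered 18863, of which 14321 had counts. The intergenic loci with counts had a median exonic length of 3155 nt and a median of 2 exons, against 7101 nt and 10 exons for coding loci with counts.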

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

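The restriction to loci with at most 10% shared exonic bases was chosen after seeing the data. The count of changed loci ranged from 5143 (without day 6 replicate 2) to 8890 (without day 0 replicate 2) around 7543, higher loci from 2547 to 4530, lower loci from 2596 to 4361, and loci changed at least 2-fold from 4226 to 5817, each within 1.5 times the main count. No locus was called in the opposite direction under any alternative, and 68.1% (without day 6 replicate 2) to 99.8% of the main calls tested there were shared. XLOC_004337 (1.83 to 2.1), XLOC_016830 (9.76 to 10.14) and XLOC_008497 (-8.51 to -7.24) kept direction and call in all alternatives run. XLOC_003220 had no value at a minimum of 50, which removed it. The odds ratio of a change for noncoding and unannotated against coding loci was 0.92 without a filter (adjusted p = 0.0432), 1.17 at a minimum of 50 (0.00287) and 1.26 with plain variance estimation, without trend or robust fitting (3.37e-09), and 0.824 to 1.06 with one library left out. That of annotated noncoding loci was 0.883 at a minimum of 50 (0.128) and 1.04 with plain variance estimation (0.478), and 0.635 to 0.819 with one library left out. That of intergenic loci was 1.07 without a filter (0.207), 1.10 with quantile normalization (0.143), 0.973 among loci with little shared sequence (0.635), 1.55 at a minimum of 50 (1.01e-08), 1.46 with plain variance estimation (1.92e-12), and 0.991 to 1.33 with one library left out. That of antisense loci was 1.29 with plain variance estimation (0.0198), and 0.893 to 1.11 with one library left out. The cause of these shifts was not tested. Mean r between stages moved to 0.913 with a pseudocount of 5 and to 0.864 at a minimum of 50, and r between day 6 replicates to 0.995 with a pseudocount of 5. Intergenic models fell to 6693 with at least 2 exons, by construction. Rises among calls ranged from 45.6% (edgeR) to 54.3% (minimum of 50). Tests of gene lists and key genes, and their alternatives, were not run, because the files give no gene names.

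The stages share replicate numbers. Deviations of same-numbered libraries from their stage means correlated at 0.176, 0.134 and 0.074, not all over 0.1, so the numbers were not taken to pair the libraries. Each library correlated best with its own number, a hint from the data and not from the design. With the replicate block 7852 loci changed, 3898 higher and 3954 lower.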

Other observations

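All tests on chromosomes, runs of loci and neighbouring loci were added to the plan after the main results had been seen; among the explanations weighed, the tests by quintile of mean level and of a single deviating day 0 library were chosen only after the result they bear on was seen.

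Loci of the X chromosome changed more often and rose more often than other loci. Of 605 tested X loci 331 changed (54.7%), 209 higher and 122 lower at day 6. The odds ratio against other chromosomes was 1.56 for a change (adjusted p = 3.41e-06) and 1.73 for a rise among calls (adjusted p = 4.18e-05). The share of rises, 63.1%, lay 13.3 points above that elsewhere, and 10.4 to 16.5 points above it over 17 alternatives. Chromosome 4 went the other way, with 193 higher and 280 lower loci (40.8% rises, adjusted p = 0.000244, -10.2 points, range -13.5 to -7.2). Chromosome 15 had 41.8% rises (adjusted p = 0.0173, -8.9 points, range -9.3 to -6.1) and chromosome 3 57.5% (adjusted p = 0.0477, 7.5 points, range 5.9 to 9.7). The family was 40 two-sided Fisher's exact tests across loci, and adjacent loci are not independent.

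Runs of at least 6 adjacent tested loci that all changed the same way numbered 17 for rises and 27 for falls, against means of 1.6 and 1.5 in 1000 shuffles of the loci (permutation p = 0.001 each, the smallest these shuffles can give). Among the 11963 loci with at most 10% of their exonic bases shared the runs numbered 13 and 16, against means of 1.5 and 1.8 (permutation p = 0.001 each, again the smallest). The longest rising runs held 11 loci each. Values of overlapping loci are uncertain, so the number of loci with over 10% shared is given for each run. One lies on chromosome 2 at 74352723 to 74719197 (mm9), where 9 of the loci are coding 4 have over 10% shared (at most 74.8%) and log2 changes ran from 0.85 to 5.48. The other lies on chromosome 5 at 14910124 to 15880360, from 0.84 to 6.77, with 2 such loci (at most 12.9%). A rising run of 11 loci was reached in 1 of the 1000 shuffles (permutation p = 0.002), and a falling run of 10, the longest observed, in 2 (permutation p = 0.003). Among loci with at most 10% shared the longest rise held 9 loci (permutation p = 0.015) and the longest fall 14, above the shuffled maximum of 11 (p = 0.001 by permutation, the smallest). Runs in that set pass over the tested loci left out of it. The fall of 14 skips loci that were not called lower, since the longest fall over all tested loci held 10. On chromosome 12 at 88766740 to 89562462, 10 adjacent loci fell, from -4.54 to -0.48, with 2 loci over 10% shared (at most 59.1%). On chromosome 13 at 23659686 to 24083083, 9 coding loci fell, from -3.62 to -0.90, with 3 such loci (at most 54.4%). On chromosome 7 at 149620610 to 149856261, 9 loci rose, from 0.81 to 7.36, with 1 such locus (63.9%). These runs of 9 loci are examples. Other runs of 9 rose on chromosomes 7, 17 and X and fell on chromosomes 4 and 9.

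Changed unannotated intergenic loci mostly fell from day 0 to day 6. Stray ends of annotated transcripts within 5 kb do not reach the loci farther away, where the gap to coding loci was larger. Of called pairs with a coding locus under 5 kb apart, 91.3% went the same way. Ends that follow their gene could therefore pull nearer loci towards the coding share, so the near and far gaps do not decide this explanation. Among the 1125 intergenic loci at least 5 kb from any annotated transcript, rises lay 29.1 points below the coding share (95% interval 25.4 to 32.8), and nearer loci 15.8 points below. That coding share was not matched for level, and ends reaching beyond 5 kb were not tested. The intervals in this paragraph treat loci as independent, which adjacent loci are not. Low counts are argued against in the third quintile of mean level, where the gap was 28.2 points (16.7 to 39.8). That quintile held 58 of the 788 intergenic calls, and the lowest and second held 447 and 274. In those lower quintiles low counts cannot be told apart from a real excess. The gaps there were 5.7 points (0.3 to 11) and 13.7 points (7.7 to 19.5), and both intervals reach within the 10 points set as the bound. The authors' normalization stays open as part of the cause. Quantile normalization narrowed the gap from 25.8 to 12.1 points (8.5 to 15.7), while TMM left 23.8. A difference between the stages themselves, and RNA of other cells such as the feeders at day 0, stay open too and were not tested apart from these. The definition of the unannotated loci by the assembly of these same stages also stays open and was not tested.

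Undifferentiated replicates differed more from one another than embryoid body replicates. Sampling of reads is argued against, since among 7274 loci with at least 1000 normalized counts in all 6 libraries the median SD at day 0 was 3.36 times that at day 6. Normalization is argued against by a ratio of 2.82 after quantile normalization, and a single deviating library by the closest day 0 pair, which differed 2.17 times as much as the most different day 6 pair. RNA of other cells in varying amounts, such as the feeders the labels mention, cannot be told apart from varying states of the ES cells. Falls made up 52.1% of calls among the 5% of loci with the largest day 0 SD and 49.5% among the others. This excess of 2.6 points (95% interval -3.1 to 8.3) is within sampling error, even with loci taken as independent. Variation between the undifferentiated cultures themselves stays open and was not tested.

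Over 1571 pairs of an intergenic locus and its nearest coding locus the log2 changes correlated at r = 0.339 (rho = 0.312, permutation p = 0.0001, the smallest that 10000 shuffles can give, adjusted p = 0.0001 over 11 sets of pairs), across loci that are not independent, and 305 of 411 pairs with both called went the same way (74.2%), against 1908 of 2903 adjacent coding pairs (65.7%, r = 0.184). Pairs over 50 kb apart, with 61.1% (r = 0.211), lay below that background share. So did pairs with the intergenic locus downstream on the opposite strand, with 59.7% (r = 0.235). By r, however, both sets lay above the background's 0.184. The adjacent coding pairs were not matched for distance and could overlap, which the intergenic pairs could not. The highest r was 0.571, for 452 pairs under 5 kb apart. Position on the same chromosome is argued against, as shuffling partners within chromosomes gave at most 0.114 against 0.339. Reads from extended transcripts of the coding locus, and a shared response of neighbours to differentiation, which was not tested, stay open: 536 pairs on opposite strands at least 5 kb apart had r = 0.312 (upper shuffled bound 0.087), but without counting known to use strand, reads of an extended transcript can fall on either strand's locus.

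For the 7543 changed loci, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split was the 1 split with as many limma calls, and the highest of the others gave 0, with 15 to 227 loci at an unadjusted p under 0.05. edgeR gave 0 and DESeq2 at most 1 in those splits. Every other split mixes the stages in both groups, so the stage difference adds to the spread within groups and few calls can arise. Their counts therefore do not measure the rate of false calls.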
